A study of Mus musculus with 9 samples.

How the data were processed

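RNA was measured on 9 Affymetrix expression arrays, 1 for each sorted sample of granulocyte-macrophage progenitors (GMPs). The labels give 3 genotypes of the floxed Dicer1 gene with 3 arrays each, called wild type, heterozygous and null here. Per the labels' protocols, the RNA came from sorted cells lysed in RLT buffer and purified with a micro-scale column kit, and was labelled with biotin by the manufacturer's standard procedure.

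The values analysed were MAS5 signal intensities as deposited, 1 number per probe set and array, with MAS5 named in the submitters' processing notes and no version or settings given there. The deposited intensity values are linear and positive, and their 2% trimmed mean was 100 on every array, so the arrays had been brought to a common level before deposit. Such scaling sets the average brightness of all arrays equal, and a change shared by most transcripts cannot be seen after it. Scanner files and detection calls were not used here, so which probe sets stood above background on an array is unknown. For arrays there is no read depth, and the number of arrays limits the precision.

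The table held 45101 probe sets, of which 64 were controls. Gene names came from the platform annotation. It gave 1 gene symbol to 34945 probe sets, several to 932 and none to 9160. Entrez identifiers of 34741 probe sets with 1 symbol matched the RefSeq gene table of mouse assembly GRCm38.p6, and 0 symbols changed. No gene was named from a probe set with several symbols. Of the probe sets of a gene, the one with the highest mean log2 value over the 9 arrays stood for it, which gave 18193 genes. Signals were transformed as log2(signal + 12), the pseudocount being an eighth of the trimmed mean rounded to a whole number. Fold changes are on that scale and understate the change of dim genes. Genes were tested where their mean reached the 40th percentile of all probe sets' means, a signal of 8.49, which kept 12347 genes and left 5846 untested.

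Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) on all 9 arrays and 3 groups together, with 6 residual and 8.1 prior degrees of freedom. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with calls at an adjusted p under 0.05. Standard errors (SE) of log2 changes are those of this fit. An exact permutation test of 3 arrays against 3 cannot give a p under 0.1. Nothing in the labels says which samples came from separate fetal livers, and 1 fetal liver was typically given to more than 1 recipient. The p-values therefore measure the spread between these samples, part of which may be technical or within a donor.

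Gene lists numbering 26 with 661 entries, of which 518 were tested, were compiled from general knowledge: granule, monocyte, dendritic, stem cell and lineage markers, cell cycle, p53, apoptosis, small RNA, decapping, interferon, NF-kB, immediate early and heat shock genes, and described targets of microRNAs. Some genes stand in several lists. Lists with 5 or more tested genes were tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01, adjusted over the 26 lists of a comparison. The same test was run with a correlation estimated for each list, and fry was run beside it. In fry, the directional p asks whether a list's genes move, on balance, one way, and the mixed p whether they change in either direction. Neither compares the list with other genes.

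Genes are named by a rule. It takes, for each comparison, the 10 largest rises and 10 largest falls among called genes whose 3 against 3 values do not overlap, the 4 members of each list with the smallest p in null against wild type, and Dicer1. List members named outside this rule, where a count was small, were chosen after their values were seen. The design, lists, naming rule and the alternatives below were fixed before the data were examined. The alternatives changed the pseudocount, the filter, the normalization (quantile or cyclic loess), the variance prior, the arrays in the fit, array weights, the treatment of several probe sets, the replicate number as a block, the inter-gene correlation and the set test, and left out each array in turn.

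The fit was tested on simulated arrays with the spread of the real ones, 12347 genes and 200 of them changed. For null against wild type, 79% of the genes changed by 2-fold and 38% of those changed by 1.5-fold were recovered, with 4 false calls. For heterozygous against wild type, 79% and 42% were recovered with 10 false calls, and for null against heterozygous 78% and 37% with 7. In each, 0 of the changed genes were called with the wrong sign. A raised list gave a camera p of 1.98e-18, 3.57e-19 and 1.62e-14 in these comparisons, and a flat list 0.574, 0.879 and 0.575. The simulated genes were drawn independently of each other. These p-values therefore do not test camera on lists of correlated genes, and 1 flat list per comparison cannot give a rate of false calls. Figures were drawn with matplotlib 3.10.9. MicroRNA seed matches in 3′ untranslated regions were not analysed here.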

Results

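Gene expression was profiled in EYFP-positive GMPs, the bone marrow progenitors that give rise to neutrophils, monocytes and related cells. The cells came from the marrow of irradiated C57BL/6 recipients that had been given fetal liver cells. In the donor cells a Cebpa-driven Cre recombinase removes floxed Dicer1 sequence and switches on the EYFP reporter. Dicer1 encodes the ribonuclease that cuts microRNA precursors into mature microRNAs. The 9 arrays fell into 3 groups of 3, wild type, heterozygous and null for Dicer1. Each array had a trimmed mean signal of 100, and their median signals ranged from 12.4 to 16.1. Across the genes tested, log2 signals correlated at 0.9835 to 0.989 between arrays of the same genotype and at 0.9721 to 0.985 between genotypes. The comparisons ask which transcripts differ in these progenitors when, by the labels, 1 or both copies of Dicer1 are deleted.

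Arrays differed in ways other than genotype. Wild-type replicate 2 had an Xist signal of 2610 and an Eif2s3y signal of 1.13. The other 8 arrays had Xist signals of 16.4 to 30.2 and Eif2s3y signals of 622 to 859. Xist is transcribed from the inactive X chromosome and Eif2s3y lies on the Y chromosome, and the labels describe every sample as female without saying whether this means the recipient or the donor cells. The sorted cells carried the EYFP reporter of the donors, so these signals are those of donor cells. They argue against female donor cells for the 8 arrays, though not for wild-type replicate 2. The wild-type group therefore differs in sex within itself. A control probe set for the 5′ part of 18S ribosomal RNA read 2746 ± 331 (SD, n = 3) on heterozygous arrays, 1314 ± 544 on wild-type arrays and 1553 ± 252 on null arrays. The control probe set for the 3′ end of Gapdh read 3794 ± 357, 3598 ± 72.1 and 3744 ± 96.5 on the same groups.

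Dicer1 itself was lowest on null arrays. Its brighter probe set had a mean signal of 232 ± 11.1 (SD, n = 3) in wild type, 185 ± 16.1 in heterozygous and 105 ± 9.46 in null cells. The fall in null against wild type was -1.07 on the log2 scale (SE 0.11, limma adjusted p = 1.88e-05), and in null against heterozygous -0.76 (adjusted p = 0.000429). Heterozygous against wild type gave -0.31 with an adjusted p of 0.217, which did not pass, although the 3 heterozygous values all lay below the 3 wild-type values. Its other probe set read 126 ± 8.77, 72.1 ± 6.06 and 51.5 ± 4.98 in the same order. In a limma fit over probe sets it gave -1.12 in null and -0.72 in heterozygous against wild type (SE 0.12 in both, unadjusted p = 5.95e-07 and 5.5e-05). The labels do not say which exon is removed or where the probes lie, so these signals cannot show whether the deletion was complete.

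**Figure D1:**
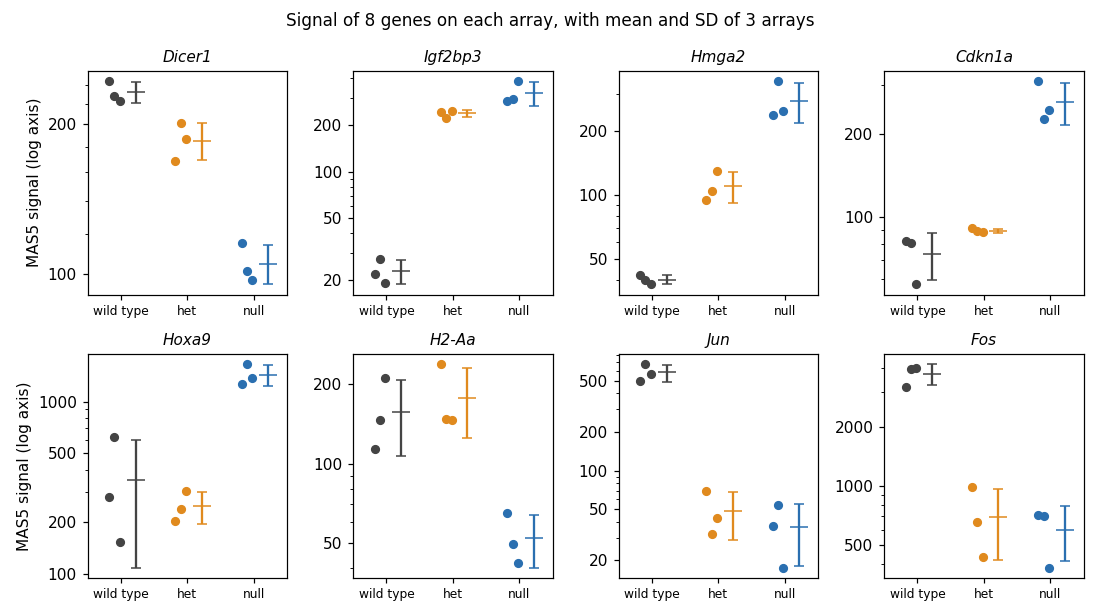
MAS5 signal on a log axis for 8 genes, with each array a point and the mean and SD of each group of 3 arrays beside the points. Dicer1 falls from 232 in wild type to 105 in null cells, Hmga2 rises from 40.1 through 110 in heterozygous to 277 in null cells, Cdkn1a and Hoxa9 are higher on null arrays alone, and Jun and Fos are lower on heterozygous and null arrays alike.

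In null against wild-type GMPs the largest rises included 2 genes described as let-7 targets that are typical of fetal cells. Igf2bp3, an RNA-binding protein, rose by 3.25 on the log2 scale (SE 0.13, adjusted p = 3.59e-09), and Hmga2, a chromatin protein, by 2.46 (SE 0.15, adjusted p = 2.65e-07). The interferon-inducible gene Ifi202b rose by 4.74, from a mean signal of 0.813 to 331, the transcript BC018473 by 3.17, the actin-binding protein gene Cttn by 3.05 and the homeobox gene Hoxa9 by 2.19, from 352 to 1424. Gdpd3, Cav2, Nebl and Ifitm1 rose by 2.42, 2.32, 2.14 and 2.03. The largest falls were in stress-responsive genes, Jun (-3.68, SE 0.26), Dusp1 (-2.91), Egr1 (-2.71), Fos (-2.65) and Hspa1b (-2.07), in the histone gene H3f3b (-2.92), in the IgE receptor chain Fcer1a (-2.25), in the neutrophil granule genes Ngp (-2.12) and Ltf (-2.09), and in Galc (-2.04), an enzyme of galactolipid breakdown. By the naming rule, each of these 20 genes separated the 3 null from the 3 wild-type arrays.

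Of the 12347 genes tested, 1937 changed in null against wild type, 938 higher and 999 lower, and 96 and 68 of them by at least 2-fold. An unadjusted p under 0.05 was reached by 3578 genes, against 617 by chance. The 3 against 3 values did not overlap for 33.03% of the genes, where chance gives 10%. Without null replicate 3, 1256 genes passed. Without wild-type replicate 2, whose sex-linked genes stood apart, 1444 did. Hspa1b did not pass without wild-type replicate 1 (adjusted p = 0.0526), and another probe set of Cav2 gave -0.11 (adjusted p = 0.856).

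Described targets of microRNAs were higher in null cells in 3 of the 5 lists. The miR-17~92 list rose, with a median of 0.26 over 31 genes (camera adjusted p = 2.83e-06; adjusted p = 0.0646 with an estimated correlation), and 11 members rose and 0 fell. They included the TGF-beta receptor Tgfbr2 (1.23, SE 0.10), the cell cycle inhibitor Cdkn1a (1.67, SE 0.14), Hif1a (0.74), Map3k5 (0.68) and the death-promoting Bcl2l11 (0.80). Adjusted over the list alone, 11 members rose as well. The let-7 list rose, with 6 of 19 genes higher and 9 adjusted over the list alone (camera adjusted p = 9.9e-05; adjusted p = 0.0646 with an estimated correlation). Besides Igf2bp3 and Hmga2 it held Tgfbr1 (1.01) and Plagl2 (0.71), other probe sets of which gave -0.04, 0.03 and 0.49, none past the threshold. In the miR-223 and miR-142 list, 7 of 24 genes rose and 1 fell, adjusted over the list alone too (camera adjusted p = 0.0064; adjusted p = 0.0646 with an estimated correlation). Its rises were led by the integrin Itgav (1.31), Tgfbr1, the actin regulator Cfl2 (0.80) and Igf1r (0.84), and Rhob fell by 0.46. With all probe sets of a gene averaged, this list had a median of -0.017 and did not pass (adjusted p = 0.0883, in a range of 0.000813 to 0.0883 over 23 alternatives). The miR-155 and miR-146 list did not pass (median 0.14, adjusted p = 0.0684), although it did without null replicate 3 (0.0386) or wild-type replicate 1 (0.0375). In it Bach1 (0.70), Hif1a and Smad4 (0.46) rose and Fos fell. Nor did the miR-21 and miR-29 list pass (median 0.04, adjusted p = 0.559), in which Reck, a protease inhibitor, rose by 1.71. In each of these 2 lists the counts adjusted over the list alone were those over all genes, 3 and 1 in the former and 2 and 2 in the latter. The 2 falls in the latter were Rhob (-0.46) and Dicer1 itself (-1.07), the targeted gene.

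Genes induced by p53 rose as a list (camera adjusted p = 0.00088; adjusted p = 0.0646 with an estimated correlation). In it 6 of 23 genes rose and 0 fell, adjusted over the list alone too: Cdkn1a, the repair gene Xpc (0.80), Ccng1 (0.81), Perp (1.40), Trp53inp1 (1.28) and Pmaip1 (0.80), the last of which did not pass without null replicate 3 (adjusted p = 0.0566). Interferon response genes rose, with 6 of 20 higher and 0 lower and 7 higher adjusted over the list alone (camera adjusted p = 9.9e-05; adjusted p = 0.166 with an estimated correlation). Oas1a rose by 1.14, Rsad2 by 1.11, Ifitm3 by 0.92 and Irf9 by 0.67. Genes of stem and multipotent progenitors rose, with 6 of 23 higher and 0 lower by both adjustments, the second over the list alone (camera adjusted p = 0.0198; adjusted p = 0.249 with an estimated correlation). They were Hmga2, Hoxa9, Prom1 (1.13), Hoxa5 (0.60), Bmi1 (0.30) and Hlf (0.56). The list did not pass without null replicate 2 (adjusted p = 0.0729) or with no filter on dim genes (median 0.01, adjusted p = 0.0694, in a range of 0.000342 to 0.249 over 23 alternatives), and Hlf did not pass without null replicate 1, null replicate 2, wild-type replicate 1 or wild-type replicate 3 (0.104, 0.0569, 0.0876 and 0.086). Mast cell, basophil and eosinophil genes rose as a list (median 0.40, camera adjusted p = 0.0165; adjusted p = 0.581 with an estimated correlation). In it the eosinophil granule genes Epx (0.94), Prg2 (0.63) and Prg3 (0.55) rose while Fcer1a fell, 3 and 1 of 12 by both adjustments, the second over the list alone. The list did not pass without null replicate 2 (0.172) or wild-type replicate 1 (0.174), nor did Prg2 (0.102 and 0.114) or Prg3 (0.0997 and 0.14). With no filter on dim genes the list's adjusted p was 0.0501, in a range of 0.000138 to 0.581 over 23 alternatives. Prg2 also failed without null replicate 3 (0.1) or wild-type replicate 2 (0.0528), and Prg3 without null replicates 1 and 3 (0.0567 and 0.0938) or wild-type replicate 3 (0.0528).

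Immediate early and heat shock genes, which cells switch on within minutes of a stimulus or stress, fell in null cells. Of 22 such genes 11 fell and 0 rose, 13 fell adjusted over the list alone, and the median was -0.54 (camera adjusted p = 5.57e-08; adjusted p = 0.0646 with an estimated correlation). Besides Jun, Fos, Dusp1, Egr1 and Hspa1b, Ier2 fell by 1.11. The mean signal of Fos was 3719 ± 453 in wild type, 693 ± 275 in heterozygous and 600 ± 187 in null cells (SD, n = 3). The neutrophil genes Ltf and Ngp moved with this group, Ltf from 118 ± 50.3 in wild type to 20 ± 6.95 in heterozygous and 17.2 ± 3.38 in null cells.

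Markers of myeloid maturation moved both ways. In the primary granule list (median 0.05, camera adjusted p = 0.127, and 0.0375 without wild-type replicate 1) the transcription factor gene Gfi1 (0.59), the serpin Serpinb1a (0.52), the protease gene Ctsc (0.74) and Fcnb (0.71) rose and Nkg7 fell by 0.40, 4 and 1 of 13, and 4 and 2 adjusted over the list alone. Secondary and tertiary granule genes (median -0.16, adjusted p = 0.969) had 4 of 19 higher and 3 lower, adjusted over the list alone too. Anxa1 (0.55) and Hp (0.51) rose and Slpi fell by 1.27, and another probe set of Anxa1 gave -0.85 (adjusted p = 0.0541). In the monocyte and macrophage list (median 0.07, adjusted p = 0.701) 4 of 24 genes rose and 6 fell, 5 and 7 adjusted over the list alone. Cd14 (1.14), Tlr4 (0.90) and Fcgr3 (0.37), all receptors for microbial products or antibodies, rose, and Crip1 fell by 1.24. Among dendritic cell and MHC class II genes (median -0.06, adjusted p = 0.701) H2-Aa and H2-Eb1, which encode class II chains, fell by 1.37 and 0.92, and Id2 (0.69) and Ifi30 (0.54) rose, 2 and 2 of 18 by both adjustments, the second over the list alone. Of 27 myeloid transcription factors and growth factor receptors (median -0.01, adjusted p = 0.968) 4 rose, Gfi1 and Id2 among them, and 5 fell, 4 and 7 adjusted over the list alone.

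Markers of other lineages changed in few genes. Among B lymphoid genes (median -0.15, adjusted p = 0.234) Ighm fell by 1.42 and Cd72 by 0.85, 2 of 11, adjusted over the list alone too. Erythroid genes (median -0.17, adjusted p = 0.676) had 1 of 15 lower, Blvrb (-1.13). The megakaryocyte and platelet list (median -0.07, adjusted p = 0.969) had 1 of 12 higher, Cd9 (0.41), and T and NK lymphoid genes (median -0.14, adjusted p = 0.701) 1 of 9 lower, Klrd1 (-0.65). Adjusted over the list alone, limma called 0 in these 3 lists. Blvrb did not pass without null replicates 1 and 3 (adjusted p = 0.0576 and 0.13) or wild-type replicates 2 and 3 (0.125 and 0.0544). Cd9 did not pass without null replicates 1, 2 and 3 (0.0735, 0.0989 and 0.0633) or wild-type replicates 1 and 3 (0.0936 and 0.116). Klrd1 did not pass without null replicates 1 and 3 (0.137 and 0.12), heterozygous replicates 2 and 3 (0.0571 and 0.0524) or wild-type replicates 1, 2 and 3 (0.0663, 0.137 and 0.0837). Endothelial and stromal genes (median 0.08, adjusted p = 0.676) had 0 of 10 changed by limma, over all genes or over the list alone, and Vcam1 gave 0.46 with an unadjusted p of 0.0338 and, without null replicate 2, 0.71 with an adjusted p of 0.0115.

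Cell cycle lists did not pass as groups, with medians of -0.04 for G1/S and DNA replication (adjusted p = 0.819) and -0.05 for G2/M and mitosis (adjusted p = 0.676). Ccne2 (0.63) and Rrm2 (0.27) rose in the former, 2 of 27, and Rrm2 did not pass without null replicate 1 (adjusted p = 0.0597), null replicate 3 (0.0841) or wild-type replicate 2 (0.0827), and its other probe sets gave -0.04 and 0.25, neither past the threshold. In the latter 2 of 28 rose and 5 fell, with the centromere genes Cenpa and Cenpe and the survivin gene Birc5 lower (-0.91, -0.48 and -0.53), Anln higher (0.54), and other probe sets of Cenpa at 0.08 (adjusted p = 0.863) and -2.06 (adjusted p = 0.000161). Both pairs of counts held adjusted over the list alone. Among 20 apoptosis regulators (median -0.07, adjusted p = 0.969) 4 rose and 4 fell, and 4 and 5 did adjusted over the list alone. Bcl2l11 and Pmaip1, which promote death, rose, the survival gene Bcl2 fell by 0.66 and the death-promoting Bad by 0.76. The small RNA pathway (median 0.11, adjusted p = 0.156) had 4 of 19 higher and 1, Dicer1, lower, and 5 and 2 adjusted over the list alone. The Argonaute gene Ago2 rose by 0.74, and its partners Tnrc6a and Tnrc6b by 0.79 and 0.87, with 2 of the other probe sets of Tnrc6a at -0.05 and 6 at 0.50 to 1.13. In the decapping and P-body list (median 0.03, adjusted p = 0.251) the deadenylase genes Cnot6 (0.73) and Cnot7 (0.49) led 4 rises among 22 genes beside 1 fall, with 4 and 3 adjusted over the list alone. NF-kB and inflammation genes (median -0.09, adjusted p = 0.645) had 1 of 18 higher, Icam1 (0.67), and 3 lower, led by the chemokine Ccl3 (-1.65), adjusted over the list alone too. Camera, which compares with all other genes, pointed up for the G1/S, apoptosis, megakaryocyte and myeloid factor lists although their medians lay below 0, and the medians of the last 3 lay above 0 after quantile or cyclic loess normalization. Camera and the median or mean also differed in sign in heterozygous against wild type for the G1/S, decapping, endothelial, mast cell, miR-155 and miR-146 and myeloid factor lists, and in null against heterozygous for the G1/S, apoptosis and primary granule lists, none of which passed.

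**Figure D2:**
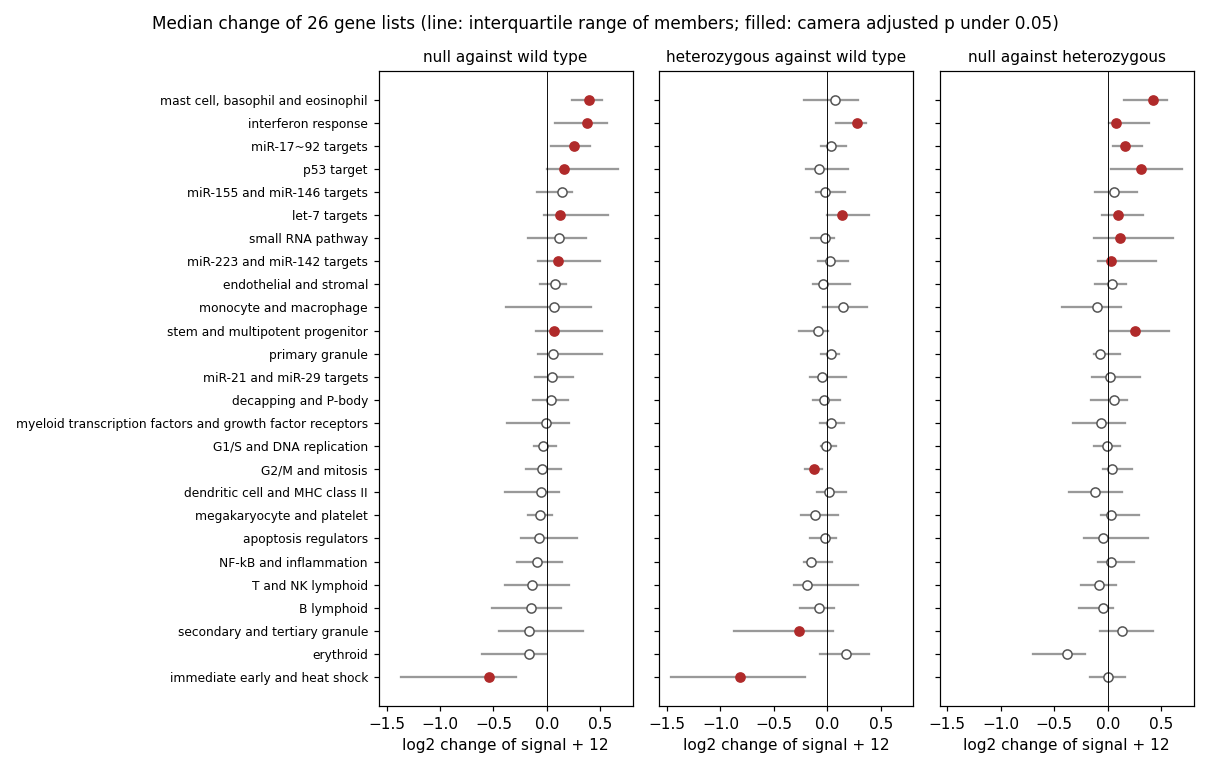
Median log2 change of 26 gene lists in each comparison, on a shared axis, with a line over the interquartile range of the members and filled points where camera's adjusted p was under 0.05. Immediate early and heat shock genes lie at -0.54 in null and -0.81 in heterozygous against wild type and at 0.00 in null against heterozygous, while the miR-17~92 list lies at 0.26, 0.04 and 0.16.

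In heterozygous against wild-type GMPs the changes were fewer, and several of the largest were those of the null cells. Ifi202b rose by 4.41 (SE 0.12, adjusted p = 1.88e-11), Gdpd3 by 2.88, Igf2bp3 by 2.85, Ncmap by 2.17, Tmem267 by 1.89, Tmem87a by 1.58, Paip1 by 1.48, Pik3ap1 by 1.45, Ifitm1 by 1.28 and the pseudogene Hmga2-ps1 by 1.25. Jun (-3.33, SE 0.26), Fcer1a (-3.11), Dusp1 (-3.09), Egr1 (-2.73), Fos (-2.47), Chil3 (-2.29), Rnf217 (-2.04), Pde4b (-2.02), Ltf (-1.97) and the chemokine Ccl3 (-1.97) fell most. By the naming rule, each of these genes separated the 3 heterozygous from the 3 wild-type arrays. Ncmap and Pik3ap1 were higher in heterozygous cells than in null cells too.

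In all 172 genes changed, 86 higher and 86 lower, with 17 and 29 of them by at least 2-fold. An unadjusted p under 0.05 was reached by 1594 genes, against 617 by chance, and 18.26% of genes had values that did not overlap, where chance gives 10%. The count fell to 97 without heterozygous replicate 2 and to 102 without heterozygous replicate 3, and was 161 without wild-type replicate 2. Ifitm1 and Chil3 did not pass without some single arrays, Ifitm1 with adjusted p-values of 0.142, 0.111 and 0.133 without heterozygous replicates 1, 2 and 3 and 0.154 and 0.124 without wild-type replicates 1 and 3, and Chil3 with 0.0511, 0.149 and 0.121 without heterozygous replicates 1, 2 and 3 and 0.098 and 0.0691 without wild-type replicates 2 and 3. Pde4b gave 0.38 (adjusted p = 0.448) without wild-type replicate 2 and -0.01 (0.984) without wild-type replicate 3, where another of its probe sets was the brightest. With all arrays, its other probe sets gave -0.12 and 0.23.

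Immediate early and heat shock genes fell in heterozygous cells, 8 of 22 with 0 higher and 15 adjusted over the list alone, with a median of -0.81 (camera adjusted p = 2.91e-17; adjusted p = 0.0492 with an estimated correlation). The let-7 list rose, with 2 of 19 genes, Igf2bp3 and Hmga2 (1.22), higher, and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00282; adjusted p = 0.103 with an estimated correlation). G2/M and mitosis genes fell as a list (median -0.13, camera adjusted p = 0.000156; adjusted p = 0.452 with an estimated correlation), with 1 of 28, Cenpf, lower (-0.53) and 2 adjusted over the list alone. Interferon response genes rose as a list, with 1 of 20, Oas1a (0.63), and 2 adjusted over the list alone (camera adjusted p = 0.00532; adjusted p = 0.452 with an estimated correlation, and 0.127 without wild-type replicate 3). Secondary and tertiary granule genes fell as a list (median -0.27, camera adjusted p = 0.0414; adjusted p = 0.852 with an estimated correlation). In it Ltf, Ngp (-1.86), Lcn2 (-1.78) and Chil3 fell and Anxa1 (0.42) and Ltb4r1 (0.66) rose, 4 and 2 of 19 by both adjustments, the second over the list alone. It did not pass without heterozygous replicate 2 (adjusted p = 0.0698) or wild-type replicate 3 (0.139), nor above the 60th percentile of brightness (0.233, in a range of 0.00436 to 0.852 over 22 alternatives, 14 of which passed). The heterozygous arrays, on which these lists moved, were also those with the brighter 18S ribosomal RNA control. The immediate early, let-7 and interferon lists moved the same way in null against wild type (medians -0.54, 0.12 and 0.38). Between those groups the 5′ control overlapped, at 1338 to 1830 on null and 907 to 1932 on wild-type arrays. The other 21 lists did not pass, the miR-17~92 list among them (median 0.04, adjusted p = 0.21, 0 of 31 changed and 2 higher adjusted over the list alone) and the p53 list (median -0.08, adjusted p = 0.875, 0 of 23 by limma over all genes or over the list alone). Some passed without a single array, the monocyte and macrophage list without heterozygous replicate 2 (0.0492), wild-type replicate 1 (0.0042) or wild-type replicate 3 (0.0194), and the NF-kB list (0.0437) and the erythroid list (median 0.55, adjusted p = 6.16e-06) without wild-type replicate 2.

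The calls of the 2 comparisons against wild type overlapped, with 59 genes higher in both, 60 lower in both and 7 opposite. Independent lists of these sizes would share 6.53 and 6.96. Unchanged groups set against the same wild-type arrays shared 0.15 on average over 20 simulations. With no gene changed, an overlap near 0 is set in advance. The simulation therefore cannot show how many shared calls the common arrays add to lists of the real sizes. Across genes, which are not independent replicates, the 2 changes correlated at r = 0.48 (rho = 0.37), where unchanged groups sharing the controls gave 0.50 (0.48 to 0.53). The covariance was 0.043 against a simulated 0.016, a difference of 0.027. The 3 wild-type arrays cannot be split with 2 in each part, so part of the excess may come from the shared controls.

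**Figure D3:**
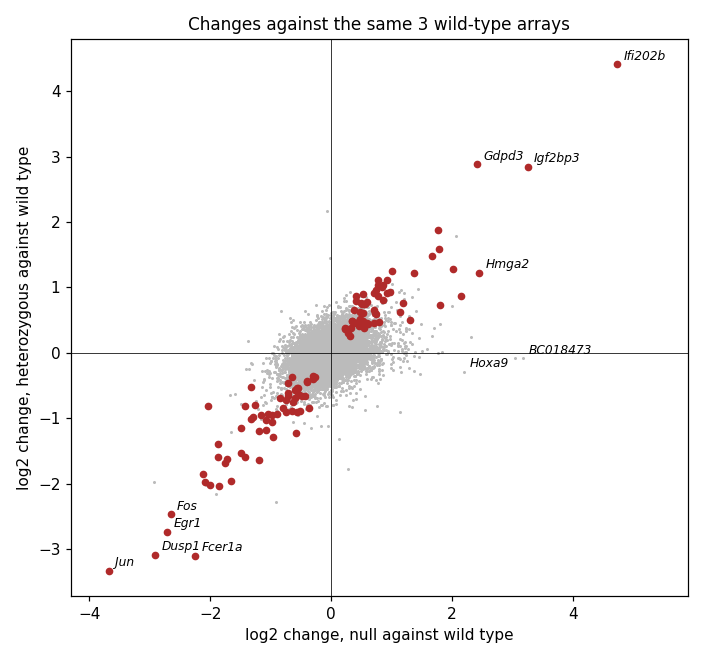
Log2 change in heterozygous against wild type (vertical) plotted against that in null against wild type (horizontal) for each of 12347 genes, with the 59 genes called higher and the 60 called lower in both comparisons in red. Ifi202b, Igf2bp3 and Gdpd3 lie far up in both and Jun, Dusp1, Egr1, Fos and Fcer1a far down, while Hoxa9 and BC018473 lie to the right near the horizontal axis.

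Null against heterozygous GMPs set cells labelled as lacking Dicer1 beside cells labelled as lacking 1 copy. BC018473 rose by 3.25 (SE 0.21, adjusted p = 1.25e-06), Cttn by 3.13, Hoxa9 by 2.49, Cav2 by 2.08, the neutrophil granule gene Lcn2 by 2.07, Cd14 by 2.04, the nuclear receptor corepressor Lcor by 1.82, the desmosomal gene Dsp by 1.80, Asph by 1.78 and Mfsd6 by 1.65. Ncmap (-2.23), the class II gene H2-Aa (-1.55), Pik3ap1 (-1.47), Haao (-1.47), Galc (-1.23), Lsp1 (-1.20), the immunoglobulin gene Ighm (-1.17), Rpp21 (-1.17), Pla2g12a (-1.15) and Smim27 (-1.14) fell most. By the naming rule, these genes separated the 3 null from the 3 heterozygous arrays. Other probe sets of Asph gave -0.15 to 0.18, none past the threshold. Of the other probe sets of Ighm, 1 gave -1.19 (adjusted p = 0.000735) and 4 gave 0.09 to 0.44, none of the 4 past the threshold. Smim27 did not pass without null replicate 3 (adjusted p = 0.0533), nor Rpp21 without heterozygous replicate 1 (0.0718) or 2 (0.0567).

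In this comparison 1770 genes changed, 845 higher and 925 lower, of which 81 and 23 by at least 2-fold. An unadjusted p under 0.05 was reached by 3442 genes, against 617 by chance, and 32.68% of genes had values that did not overlap, where chance gives 10%. Without heterozygous replicate 1 the count was 1033, and without null replicate 3 it was 1065. Of the genes changed in null against wild type, 558 were also higher and 564 also lower in null against heterozygous, and 6 were opposite. Independent lists would share 64.2 and 74.8. Unchanged groups sharing the null arrays shared 0.05 on average over 20 simulations, a value again near 0 in advance and no measure of what the shared arrays add. The changes in null against wild type and in null against heterozygous correlated across genes at r = 0.71 (rho = 0.70). Unchanged groups sharing the null arrays gave 0.50 (0.48 to 0.53), and the covariance was 0.079 against a simulated 0.016, a difference of 0.063.

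The p53 list rose again, 9 of 23 with 0 lower, and 11 and 1 adjusted over the list alone (median 0.31, camera adjusted p = 0.00024; adjusted p = 0.0705 with an estimated correlation), with Cdkn1a higher by 1.41, Pmaip1 by 1.20 and Xpc by 0.71. Stem and multipotent progenitor genes rose, 6 of 23, adjusted over the list alone too, with Prom1 (1.35) and Hoxa9 among them (camera adjusted p = 0.000315; adjusted p = 0.149 with an estimated correlation). The miR-17~92 list rose, 7 of 31 with 1 lower by both adjustments, the second over the list alone (camera adjusted p = 0.000315; adjusted p = 0.149 with an estimated correlation), and Tgfbr2 was higher by 1.22. Lists with weaker calls rose too: mast cell, basophil and eosinophil genes (adjusted p = 0.0172; adjusted p = 0.694 with an estimated correlation), miR-223 and miR-142 targets (0.0323; adjusted p = 0.149 with an estimated correlation), let-7 targets (0.0406; 0.165 likewise), the small RNA pathway (0.0406; 0.317 likewise) and interferon response genes (0.0475; 0.606 likewise). In these 5 lists 3, 7, 4, 6 and 4 genes rose and 0, 1, 1, 1 and 0 fell, of 12, 24, 19, 19 and 20. Adjusted over the list alone 4, 7, 5, 8 and 4 rose. Each of the 5 lost its call without some single array. The mast cell list did without null replicate 2 (0.0978), the miR-223 and miR-142 list without null replicates 1, 2 and 3 (0.0564, 0.0506 and 0.109) or wild-type replicate 3 (0.0596), and the let-7 list without null replicate 1 (0.0564), heterozygous replicates 2 and 3 (0.0882 and 0.0678) or wild-type replicate 1 (0.0503). The small RNA list did without null replicates 1 and 3 (0.0564 and 0.0691), heterozygous replicate 3 (0.11) or wild-type replicate 1 (0.0503), and the interferon list without null replicates 1 and 2 (0.158 and 0.0506), heterozygous replicates 2 and 3 (0.0988 and 0.101) or wild-type replicate 1 (0.0503). With no filter on dim genes the mast cell list did not pass (0.0891, in a range of 0.00107 to 0.694 over 23 alternatives). With all probe sets of a gene averaged, the miR-223 and miR-142 list had a median of -0.016 (adjusted p = 0.0977, range 0.00185 to 0.149), the small RNA list of 0.008 (0.0803, range 0.0175 to 0.317), the let-7 list of 0.018 (0.272, range 0.00211 to 0.272) and the interferon list of 0.074 (0.0614, range 0.0206 to 0.606), and none of the 4 passed. The 5′ 18S ribosomal RNA control, at 1553 ± 252 on null and 2746 ± 331 on heterozygous arrays (SD, n = 3), was lower on the null arrays, on which these lists rose. Immediate early and heat shock genes did not pass here (median 0.00, adjusted p = 0.88), with 2 of 22 higher and 2 lower, adjusted over the list alone too. Of the monocyte and macrophage list (adjusted p = 0.424), Cd14 and Tlr4 (0.72) rose and 5 genes fell, among them Irf8 (-0.66), a transcription factor of the monocyte and dendritic lineages, with 2 and 9 adjusted over the list alone. Other lists passed without a single array, the G2/M list (0.0465) and the secondary and tertiary granule list (0.00362) without null replicate 2, the miR-155 and miR-146 list without null replicate 3 (0.0457) and the erythroid list without wild-type replicate 2 (0.0205). The miR-155 and miR-146 list also passed with no filter on dim genes and with fry, and the erythroid list with these 2 groups fitted alone.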

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

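The gene lists without the genes called in heterozygous against wild type were an alternative chosen after seeing the data. They left 8 lists past the threshold in null against wild type and 6 in null against heterozygous. The stem cell list in null against wild type and the interferon and let-7 lists in null against heterozygous then did not pass. For the counts that follow the cause was not tested. Without the filter on dim genes 112 genes changed in heterozygous against wild type, with 18193 genes tested in place of 12347. Without an intensity trend 1290, 83 and 1103 genes changed in null against wild type, heterozygous against wild type and null against heterozygous. With the mean of a gene's probe sets 86 genes changed in heterozygous against wild type, 4 lists passed in null against heterozygous, Anxa1 gave -0.152, and the share of higher calls went from 48.4% to 39.4% in null against wild type and from 47.7% to 39.5% in null against heterozygous. Normalization moved these shares the other way, to 55.2% (1025 higher, 831 lower) and 54.1% with cyclic loess and to 52.3% and 51.2% with quantile normalization. With 27022 probe sets in place of genes, 3030 and 278 changed against wild type in null and heterozygous cells. Above the 60th percentile of brightness 4 lists passed in null against heterozygous. With the mean of a gene's probe sets, the secondary and tertiary granule list in heterozygous against wild type did not pass (median -0.243, camera adjusted p = 0.0574). With an estimated correlation 0, 1 and 0 lists passed, against 8, 5 and 8 with the preset one, and with fry 10, 3 and 7 did. Calls of lists were lost with no filter (stem cell and mast cell lists in null against wild type, mast cell in null against heterozygous), above the 60th percentile (secondary granule in heterozygous against wild type, interferon, let-7, miR-223 and miR-142 and small RNA in null against heterozygous), with quantile normalization (let-7 in null against heterozygous), without a trend (secondary granule) and with fry (mast cell in both comparisons of null cells, G2/M, interferon and secondary granule in heterozygous against wild type, interferon in null against heterozygous). Lists that otherwise did not pass did so under some settings: in null against wild type the B lymphoid list (60th percentile, fry), the NF-kB list (fry), the miR-155 and miR-146 list (fry, and lists without genes called in heterozygous cells) and the primary granule list (mean of probe sets), in heterozygous against wild type the NF-kB list (no filter, fry), and in null against heterozygous the miR-155 and miR-146 list (no filter, fry) and the erythroid list (2 groups alone).

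Leaving out each array gave 1256 to 1939 genes in null against wild type, 97 to 169 in heterozygous against wild type and 1033 to 1896 in null against heterozygous, the lowest without null replicate 3, heterozygous replicate 2 and heterozygous replicate 1. Counts also fell by over 1.5 times without heterozygous replicate 3 in heterozygous against wild type (102) and without null replicate 3 in null against heterozygous (1065). It gave 6 to 9, 4 to 7 and 4 to 9 lists, with 4 in null against heterozygous without null replicate 1 and 5 without heterozygous replicate 3 or wild-type replicate 1. The correlation of the changes ran from 0.42 to 0.54. Pf4 ran from -1.218 to 0.001 (without wild-type replicate 2), Kdr from -0.001 (without null replicate 2) to 0.664, Cav1 from -0.019 (without wild-type replicate 3) to 0.34 and Pde4b from -2.31 to 0.383 (without wild-type replicate 2). Of the named genes' values under the other alternatives, 1558 kept their direction and side of the threshold, 54 lost the call, 1 gained it and 1 changed sign; of those without 1 array, 1253, 64, 2 and 4 did. Whether replicate numbers pair the arrays is unclear. Deviations of arrays with the same number correlated at -0.027 to 0.143 over 9 pairs, 2 of them over 0.1. Those of arrays with different numbers correlated at -0.151 to 0.092 over 18 pairs, 0 of them over 0.1. Of 9 arrays, 6 correlated best with their own number, a hint of pairing from the data and not the design. With the replicate block 2111, 201 and 1934 genes and 8, 4 and 7 lists passed. The secondary and tertiary granule list in heterozygous against wild type (0.0752, in a range of 0.00436 to 0.852 over its 22 alternatives), the interferon list in null against heterozygous (0.051, in a range of 0.0206 to 0.606 over 23) and Dcp1a in null against wild type did not pass with it. Signal over background is unknown without detection calls, which limits what can be said of dim genes.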

Other observations

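The tests of neighbouring genes, of wild-type replicate 2 and of the splits of the arrays were set before their results were seen. The tests of Dicer1's chromosome, the shortened let-7 list, single wild-type arrays behind the immediate early genes, S100a8 and S100a9, brightness and shared genes were chosen only after the result, or values it rests on, had been seen. So was the count of batch labels.

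Cytokine receptor and monocyte genes outside those named so far moved both ways in null against wild-type cells, and were chosen after their values were seen. Csf2rb and Csf2rb2, chains of the receptors for granulocyte-macrophage colony-stimulating factor and interleukins, rose by 0.53 and 0.46, and Csf3r, the receptor for granulocyte colony-stimulating factor, fell by 0.38. The chemokine receptor gene Ccr2 rose by 0.75 and the lysozyme gene Lyz2 by 0.82, while Cd68, Ms4a6c, Ctss and Klf4 fell by 0.48, 0.40, 0.44 and 0.66. Among G2/M genes, Ube2c fell by 0.52 and Ect2 rose by 0.53. These calls are limma's at an adjusted p under 0.05, and the genes were not refitted under the alternatives.

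Of the 119 genes called alike in heterozygous and null against wild type, 26 had another such gene among the 5 tested genes on either side, such as Ifi202b beside Mndal and the let-7 target Igf2bp3 beside Gsdme, where random draws gave 10.8 on average and mostly 4 to 20 (permutation p = 0.0013, 10000 draws). Segments of donor-strain chromosome are a candidate explanation, and 11 of the genes lay on Dicer1's chromosome against 4.13 by its share (Fisher's exact p = 0.0028). Of the genes changed in null against both others, 52 lay on that chromosome against 38.8 (1.34-fold, beside 2.67-fold for the former, the difference not tested; Fisher's exact p = 0.032), 22 of the 119 with the largest change had a neighbour (permutation p = 0.012), and of the 40 genes nearest Dicer1 17.5% were called in null against wild type, against 15.7% of all genes (Fisher's exact p = 0.668). Wild-type replicate 2 is argued against as the whole source, since 80 of the 119 genes (67.2%) stayed called in both without it. The let-7 list without Hmga2 and Igf2bp3 had a median in heterozygous against wild type at the 97th percentile of brightness-matched random lists, and the labels give C57BL/6 as the strain of the recipients and the donors by genotype alone, so segments and a response of let-7 targets to the loss of 1 copy, a hypothesis, both stay open.

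Immediate early genes were lower in heterozygous and null than in wild-type cells. A single wild-type array is argued against as the source, since at least 7 of the 11 called members stayed called in null against wild type without any 1 of them. Mature neutrophils in the wild-type sort, which a progenitor gate would remove, may contribute. The mean change of S100a8 (signal 2619 in wild type, 2248 in heterozygous) and S100a9 (2178 and 1362) was -0.45 in heterozygous and -0.07 in null against wild type. It lay above the list's median by 0.36 and 0.47, with an SE of 0.57 from an ordinary linear model of the mean of both genes. The limma SEs were 0.29 and 0.46 for each gene. The SE of 0.57 is that of the mean change alone and leaves out the spread of the list's median. Both differences are under 2 such SE, which leaves this undecided. Granule genes of neutrophils moved both ways. Ltf fell in heterozygous (-1.97) and null (-2.09) against wild type. Ngp fell in both as well, from a mean signal of 476 in wild type to 116 in heterozygous and 98 in null cells (-2.12 in null). Chil3 (-2.29) and Lcn2 fell in heterozygous cells. Of 19 secondary and tertiary granule genes, 4 fell and 2 rose in heterozygous and 3 fell and 4 rose in null against wild type. The labels used here record no batch, so the count of batch labels that hold more than 1 genotype was 0 in advance. Handling of the wild-type samples apart from the others therefore cannot be told apart from genotype. An effect of Dicer1 itself stays open and was not tested.

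Camera at the preset correlation called 3 of 5 lists of described microRNA targets higher in null than in wild-type cells. With an estimated correlation each of the 3 had an adjusted p of 0.0646 and did not pass. Brightness of the lists' genes is argued against for 4 of the 5 lists (let-7, miR-17~92, miR-223 and miR-142, miR-155 and miR-146), whose medians lay above 95% of brightness-matched random lists. The miR-21 and miR-29 list lay at the 87.3rd percentile (median 0.044). It was left out of the test's count, which was set after values had been seen. Genes held by more than 1 of these lists, or also by the p53 target list, may account for part of the pattern. Without them 1 of 4, the miR-17~92 list, stayed above that level (median 0.256 before and 0.225 after, 100th percentile). The miR-223 and miR-142 list went from 0.10 to 0.067 and the miR-155 and miR-146 list from 0.141 to 0.065 (89.1 and 88.4). Neither the miR-223 and miR-142 list nor the miR-155 and miR-146 list holds a gene of the p53 list. The genes taken out of them were described targets in another microRNA list. Their removal therefore cannot tell sharing from a release of targets. The drop in the median does not extend to the let-7 list, whose median was 0.118 with 19 and with 13 genes. That list lay at 94.4 as the upper bound of random lists moved from 0.091 to 0.124. Genes called in heterozygous against wild type were then left out as well. The let-7 list fell to 0.092 (percentile 87.4, 11 genes), and the miR-155 and miR-146 list had 0.094 (94.6). The miR-17~92 list had 0.225 (99.9) and the miR-223 and miR-142 list 0.067 (88.7). Release of targets from microRNAs stays open as a hypothesis, and seed matches were not tested.

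For each comparison, 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave as many changed genes, and 10 splits are too few for a share under 0.05. The real counts were 1937, 172 and 1770, and the highest among the other splits 1, 1 and 0. Each of the other splits holds arrays of both genotypes in each part. Genotype differences then count as spread, so low counts are set in advance and are no measure of chance.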
